A study of Homo sapiens with 2 samples.

How the data were processed

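The data were 2 one-colour Agilent arrays of HaCaT cells, 1 of untreated cells and 1 of cells kept for 48 h with TGF-β1. Groups were taken from the source and treatment labels; the labels do not give the dose. Total RNA was amplified and labelled with Cy3, per the labels' protocols. The scanner images were read with Agilent Feature Extraction, version 9.5.1.1 per the submitters' processing notes, whereas the module version per the file headers is 10.7.1.1. The deposited scanner files hold spot intensities on a linear scale, with background-subtracted processed signals, mean signals, local background and quality flags for each of 62976 spots, of which 60901 are not controls. Both arrays lie on the same slide. The table of processed values that the authors deposited does not state its scale. Set against the scanner values, it held linear signals after quantile normalization: each column correlated with its own array at 0.9999 over probes on the log2 scale, all sorted values lay within 1% of the mean of the sorted scanner signals, and both columns had a median signal of 5.34. It was used only as an alternative.

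From the deposited intensities, log2 of the processed signal minus the 75th percentile of each array over non-control probes was computed. The 75th percentile signal was 113 for the untreated and 105 for the TGF-β1 array. Control spots and spots marked as outliers (51 untreated, 57 TGF-β1) were left out, and spots of a probe were averaged on the log2 scale. A probe counted as well above background where at least 0.5 of its spots carried that flag. The lowest signal well above background was 10.6 on the untreated and 11.2 on the TGF-β1 array. A gene was represented by its probe that was well above background on the most arrays and then by the brightest. A gene well above background on 1 array only received a bound: the bright signal against the higher of the lowest signal well above background on the other array and the dim probe's own signal. Each difference is TGF-β1 minus untreated. The scanner's error estimate combines the errors the scanner software assigned to the processed signals of both arrays.

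Gene symbols were updated by accession through a RefSeq table of assembly GRCh38.p14, used for names and gene order only. Accessions of 31104 of 58201 probes (53.4%) matched; the other probes kept the name in the files. In all, 22826 symbols were on the arrays, and 24128 probes had only a clone, locus or transcript identifier. Coordinates are those of the probes on hg19, per the file headers. No hg19 annotation was used here, so exons and untranslated regions are not stated.

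With 1 array per group, no test between the conditions, p-value or standard error was computed, and the number of arrays limits the precision. Later shuffles and a bootstrap over genes describe these 2 arrays only. Genes were counted at a 2-fold threshold. Technical noise was taken from probes printed as 10 spots, from spike-in controls and from different probes of a gene. For each of 42 gene lists, the median difference was placed among 10000 random lists matched on 20 bins of mean signal. Of the listed genes, 146 entries were not measured. The genes named were fixed by rule before the data were examined: 23 chosen genes, the 12 highest and 12 lowest measured on both arrays, the 5 largest bounds in each direction, and in each list up to 5 members with the largest differences and any member past 2-fold. XIST and Y-linked genes were not named. Some genes that this rule names are not reported here; they remain in the counts and list medians.

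The calculation was tested on simulated arrays made from the untreated array with measured spot noise. For the comparison of TGF-β1 with untreated, run on 14868 genes, none of 50 genes changed by 1.5-fold was called at 2-fold, and 98% of those changed by 3-fold, 96% by 8-fold and 98% by 20-fold were called. Of 14638 unchanged genes none was called. The simulation holds no variation between cultures, none between arrays beyond a constant shift and none between probes of a gene. Changed genes were drawn from those well above background on both arrays. With spot noise small against 2-fold, these results check the calculation and not the noise of real differences. A list of 30 genes shifted by 0.80 was recovered at 0.80, and 5.33% of 300 random lists of 20 genes fell outside the central 95%.

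Alternatives were normexp background correction with an offset of 50, quantile, median and loess normalization, 2 other filters on dim probes, the mean of all probes of a gene, the authors' processed values and leaving out saturated spots. As 42.2% and 40.4% of probes were well above background, the 75th percentile over probes detected on both arrays, and scaling on spike-ins, were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, R 4.3.3 and limma 3.58.1, and figures matplotlib 3.10.9.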

Results

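Gene expression was measured in HaCaT cells, an established line of immortalised human keratinocytes, after 48 h with or without TGF-β1, a cytokine that signals through SMAD transcription factors. The question, as the submitters' design states it, was how the transcriptional program differs when TGF-β1 is used to set off an epithelial-mesenchymal transition (EMT), in which epithelial cells take on mesenchymal traits. Total RNA of each culture was labelled with Cy3 and hybridised to 1 one-colour Agilent array, so the data hold 1 untreated and 1 TGF-β1 array. There are no replicates: no difference below has a replicate check, no test between the conditions was run, and the errors given for genes are technical. The arrays carried 58201 non-control probes of 60 bases. Of these, 24533 (42.2%) were well above background on the untreated array and 23502 (40.4%) on the TGF-β1 array, and no spot was saturated. Differences are log2 signal with TGF-β1 minus log2 signal untreated, each signal relative to the 75th percentile of its array. For a gene well above background on 1 array only, the value is a lower bound on the difference and is written "at least".

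Genes higher with TGF-β1 included TGF-β and SMAD targets, matrix genes and actin cytoskeleton genes, and genes lower with TGF-β1 included inhibitor-of-differentiation genes and cell cycle genes. Keratin genes past 2-fold went both ways. Of 14889 genes with a symbol and a measured signal, 911 (6.12%) were at least 2-fold higher with TGF-β1, 1013 (6.80%) were at least 2-fold lower and 12965 (87.1%) lay within 2-fold. At 8-fold the counts were 62 higher and 37 lower. The counts at 2-fold were 479 and 508 with normexp background correction, and 1562 and 1741 without a filter on dim probes. Of 308 named genes past 2-fold, 85 had a log2 difference smaller by over 1.5 times with normexp, which shrinks differences of dim genes, and 239 stayed past 2-fold. Across the genes, which are not independent replicates, the log2 signals of the arrays had a Pearson correlation of 0.959. The spread between spots and between spike-in controls was small against these thresholds, unlike that between some probes of a gene. In 281 probes printed several times, the spreads between spots within each array combined to a median SD of 0.078 for a single-spot difference. That SD holds no variation between arrays. The 8 spike-in controls differed between the arrays by −0.003 to 0.13. Different probes of a gene varied more, with an SD of 0.33 per probe. In 3726 genes with several probes, the range of the difference had a median of 0.23 and a 95th percentile of 1.02.

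Among the 12 genes with the largest positive difference on both arrays were genes for a cytokine, a matrix glycoprotein and an actin-binding protein. IL6, an inflammatory cytokine, was higher by 5.58 ± 0.29 (the scanner's error estimate), which is 48.0-fold (NM_000600, chromosome 7, hg19 22771207 to 22771266), and the matrix glycoprotein fibronectin, FN1, by 5.48. The FN1 value rests on 1 probe, on transcript NM_054034 (chromosome 2, hg19 216288217 to 216288895). Also among the 12 were the neuronal globin NGB at 4.93, the actin-binding protein gene TAGLN at 4.87, the Wnt ligand gene WNT5B at 4.79, the non-coding RNA MANCR at 4.77, the matricellular gene CCN2 at 4.76, the myosin light chain gene MYL7 at 4.72, the cystatin gene CST6 at 4.67, AMIGO2 at 4.30 and KPNA7 at 4.29. With normexp background correction IL6 was at 3.56, FN1 at 3.64, NGB at 3.26, MANCR at 2.67, CCN2 at 3.12 and KPNA7 at 2.13. Both other probes of MANCR were well above background with TGF-β1 only, with bounds of at least 1.04 and at least 3.73. Among genes not well above background in untreated cells, the largest bounds were at least 100-fold for ODAPH, at least 41.4-fold for AMTN, at least 36.4-fold for DACT1, at least 35.4-fold for HLA-DQA1 and at least 24.6-fold for LINC02551. With normexp these bounds were 3.94, 2.90, 2.54, 2.47 and 2.23 on the log2 scale. HLA-DQA1 has a near-identical paralog, so its value is uncertain.

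**Figure D1:**
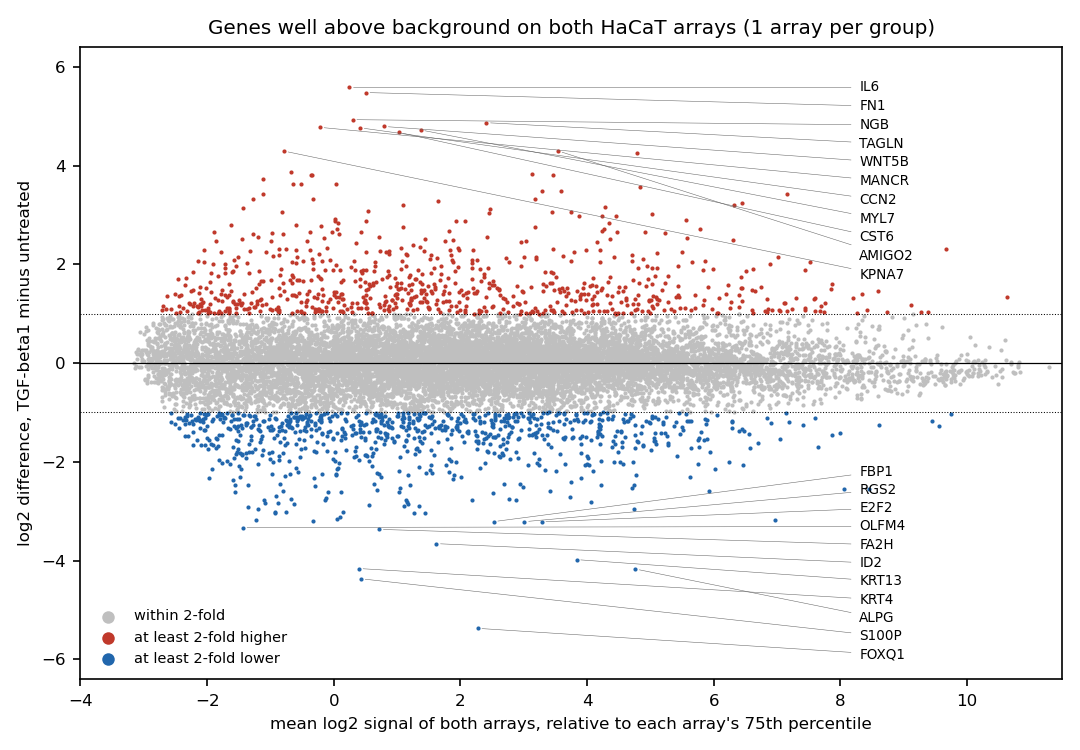
Each point is a gene well above background on both arrays, with the mean log2 signal of the arrays on the x axis and the log2 difference, TGF-beta1 minus untreated, on the y axis; dotted lines mark 2-fold. Genes named are among the 12 highest and 12 lowest, with IL6 at 5.58 and FOXQ1 at −5.37; genes not reported here are not drawn.

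The lowest gene measured on both arrays was FOXQ1, a forkhead transcription factor gene, at −5.37 ± 0.21 (the scanner's error estimate), which is 41.4-fold lower with TGF-β1 (NM_033260, chromosome 6, hg19 1314629 to 1314688). The calcium-binding protein gene S100P was lower at −4.37 and the alkaline phosphatase gene ALPG at −4.17, the latter uncertain because other placental-type phosphatase genes are near-identical to it. KRT4 (−4.16) and KRT13 (−3.98), a keratin pair of stratified mucosal epithelium, came next. The 12 lowest also included ID2 (−3.66), FA2H (−3.37), OLFM4 (−3.33), the cell cycle transcription factor gene E2F2 (−3.22), RGS2 (−3.21) and FBP1 (−3.21). With normexp KRT4 was at −2.67 and OLFM4 at −1.42. KRT1, the keratin of suprabasal epidermis, was measured in untreated cells only and was at least 119-fold lower with TGF-β1 (NM_006121, chromosome 12, hg19 53068520 to 53068579). The other large bounds were at least 23.1-fold for CYMP, at least 16.8-fold for PTGES, at least 13.1-fold for HS3ST6 and at least 12.3-fold for SOX2. With normexp the KRT1 bound was −4.28 on the log2 scale and those of CYMP, PTGES, HS3ST6 and SOX2 were −2.14, −1.90, −1.38 and −1.66.

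Genes were next read as 42 lists fixed before the data were examined. The median difference of each list is given with its percentile among 10000 random lists of the same size and matched expression, which describes these arrays and is no test of TGF-β1. Of the 42 medians, 16 lay above and 6 below the central 95% of random lists, where chance gives about 2.1 in all. Some lists share genes. The TGF-β and SMAD target list had the highest median, 2.03, above every random list: 14 of its 19 measured members were at least 2-fold higher and none was as much lower. SMAD7, the inhibitory SMAD gene, was higher by 1.93, PMEPA1 by 3.41, SKIL by 2.21 and LTBP2 by at least 4.30 (1.96 with normexp). The list of family ligands, receptors and SMADs, which also holds antagonist and latent TGF-β binding protein genes, had a median of 0.14 at the 89.7th percentile. Of its 26 measured members, 6 were at least 2-fold higher and 3 at least 2-fold lower. TGFB2 (3.63; 1.97 with normexp) and INHBA (3.49) were higher, whereas INHBB (−2.84; −1.39 with normexp) and BMP7 (−2.59) were lower. The BMP and ID target list had the lowest median of all, −2.13, below every random list, with 5 of 6 members at least 2-fold lower. ID1 was lower at −2.55, ID3 at −1.71 and ID4 at −3.05.

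Mesenchymal markers had a median of 1.55 (1.01 without a filter on dim probes), above every random list, and 8 of 13 were at least 2-fold higher. VIM, the intermediate filament vimentin, was higher by 3.81 (2.13 with normexp), TNC by 2.72, WNT5A by 2.19 (1.18 with normexp), CDH2 (N-cadherin) by 1.87 and the fibronectin receptor subunit ITGA5 by 1.55. S100A4 ran the other way at −1.85. The EMT transcription factors showed no common direction, with a median of 0.11 at the 76.1th percentile and 5 of 14 at least 2-fold higher against 2 lower. SOX4 (3.12), SOX9 (2.65), SNAI2 (1.96), TCF4 (1.62) and ETS1 (at least 1.46; 0.43 with normexp) were higher, while FOXQ1 and SNAI3 (−1.47; −0.71 with normexp) were lower. SNAI1 was dim on both arrays and stood at −0.77 ± 0.36 (the scanner's error estimate; −0.14 with normexp). ZEB1 and ZEB2 were not well above background on either array, so no difference can be given for them.

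**Figure D2:**
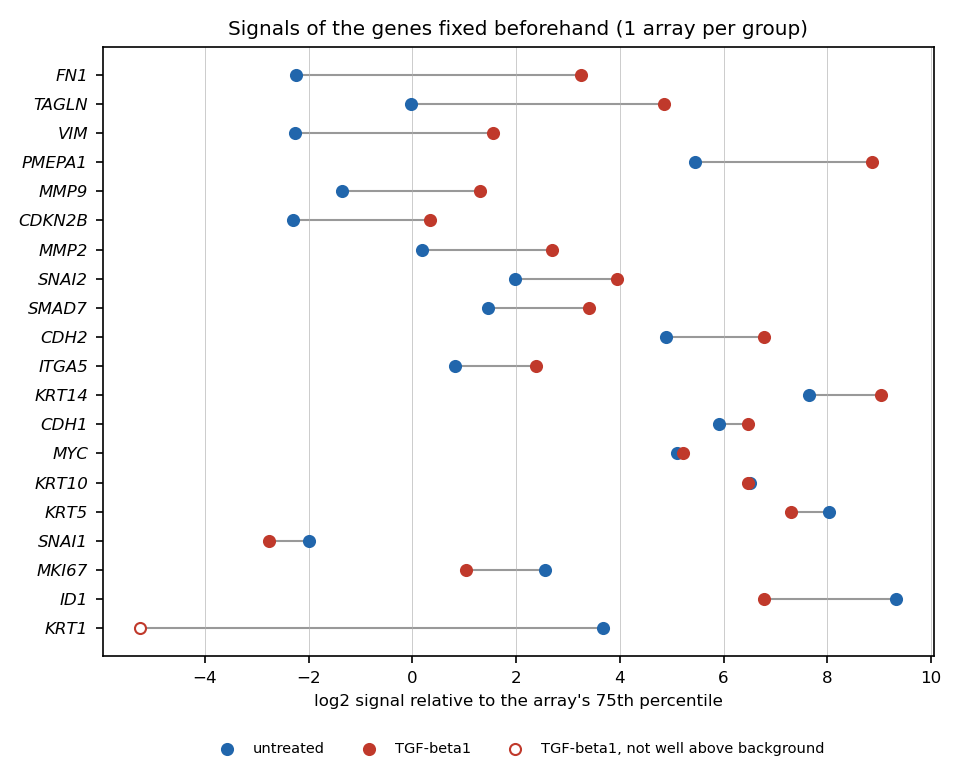
Log2 signal relative to the 75th percentile of the array is shown for 20 genes named beforehand, blue for the untreated and red for the TGF-beta1 array, with an open circle where the probe was not well above background; the genes are ordered by their difference. CDH1 and CDH2 both lie to the right with TGF-beta1, at 6.47 and 6.78 against 5.92 and 4.90.

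Epithelial junction and polarity genes were split. CDH1, which encodes E-cadherin and was printed as 10 spots per array, was 1.46-fold higher with TGF-β1 (0.55 ± 0.06, the scanner's error estimate; NM_004360, chromosome 16, hg19 68869214 to 68869273). The list median was −0.15 (−0.033 with median centring), at the 6.66th percentile, with 8 of 32 members at least 2-fold lower and 2 at least 2-fold higher. The claudin genes CLDN3 (−2.84) and CLDN1 (−2.47), PARD6A (−1.73) and OCLN (−1.12; −0.68 with normexp) were lower, and the cadherin gene CDH3 (1.08) was higher. Desmosome genes all lay within 2-fold, with a median of 0.18 over 12 genes at the 91.6th percentile. Epithelial transcription and splicing regulators had a median of −0.35 at the 1.01th percentile. In that list GRHL3 (−2.61), ELF3 (−2.04), KLF5 (−1.45) and GRHL1 (−1.42) were at least 2-fold lower, and the other 12 of 16 were within 2-fold, among them ESRP1 at −0.79.

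Basal keratinocyte and hemidesmosome genes had a median of 1.05, above every random list, and 8 of 13 were at least 2-fold higher. The laminin chain gene LAMB3 (1.46), the collagen gene COL17A1 (1.43) and BNC1 (1.05) were higher. The 2 probes of LAMA3, another laminin chain gene, disagreed, at 3.20 and −0.05. KRT14 was higher by 1.40 on the brighter of 2 probes and by 0.63 on the other, whereas its partner KRT5 was at −0.73 and KRT15 at −2.56. Keratinocyte differentiation genes had a median near 0 (−0.06, 44.1th percentile, of the other sign with median centring and without a filter on dim probes) but a mean of −0.75. Of 25 measured, 9 were at least 2-fold lower, including TGM1 (−1.57), ABCA12 (−1.52; −0.72 with normexp) and SPINK5 (at least 1.73 lower on the log2 scale; 0.39 with normexp), and 3 were at least 2-fold higher, the kallikrein genes KLK6 (1.48) and KLK5 (1.05) and SPRR1B (1.04; 0.31 with normexp). Another of the 9 lower genes had probes past 2-fold in opposite directions, and others of the 9 fell within 2-fold in some alternatives. KRT10 was at −0.06, and at 0.06 with median centring. Among wound keratins and alarmins, KRT17 (2.04) and KRT16 (1.57) were higher, and the median of 11 genes was −0.22 (22.2th percentile, of the other sign without a filter on dim probes). Among 5 simple epithelial keratins, KRT80 was higher by 2.72 and the other 4 lay within 2-fold (median 0.34, 96.6th percentile).

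Extracellular matrix lists had positive medians. For interstitial collagens and matrix proteins it was 1.28, above every random list, with 13 of 23 at least 2-fold higher, among them SPOCK1 (2.98), THBS1 (2.98), COL5A1 (2.89) and COL1A1 (1.28), and FBLN1 at least 2-fold lower (−1.01; −0.58 with the mean of all probes). Without the filter on dim probes that median was 0.37, and with normexp background correction 0.68. Basement membrane genes had a median of 0.68, with 5 of 17 at least 2-fold higher, led by the type IV collagen genes COL4A1 (2.75) and COL4A2 (1.88). Collagen-modifying enzymes had a median of 0.47 (99.9th percentile), with the transglutaminase gene TGM2 (at least 2.98; 1.09 with normexp) and BMP1 (1.49) past 2-fold. Matrix proteases and their inhibitors had a median of 0.80, with 13 of 27 at least 2-fold higher and 3 lower. The gelatinase genes MMP9 (2.65; 1.75 with normexp) and MMP2 (2.52) and the urokinase gene PLAU (2.49) were higher, and MMP12 (−2.59; −1.38 with normexp), MMP1 (−2.46) and PLAT (−1.04) were lower. Integrins had a median of 1.13, with 10 of 17 at least 2-fold higher, led by ITGB6 (3.73; 1.78 with normexp), and ITGA7 lower (−1.17; −0.77 with normexp). Of 34 actin cytoskeleton and contractility genes, 20 were at least 2-fold higher and none as much lower (median 1.09), including CALD1 (3.56), TPM1 (3.24) and MYL9 (2.63). YAP/TAZ targets had a median of 0.99, with 7 of 15 at least 2-fold higher, among them ANKRD1 (at least 3.45; 1.28 with normexp) and F3 (2.54). The medians for basement membrane, protease, integrin, actin and YAP/TAZ genes exceeded every random list. With normexp background correction the basement membrane median was 0.28, the protease median 0.37 and the integrin median 0.70, and without a filter on dim probes the protease median was 0.42.

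**Figure D3:**
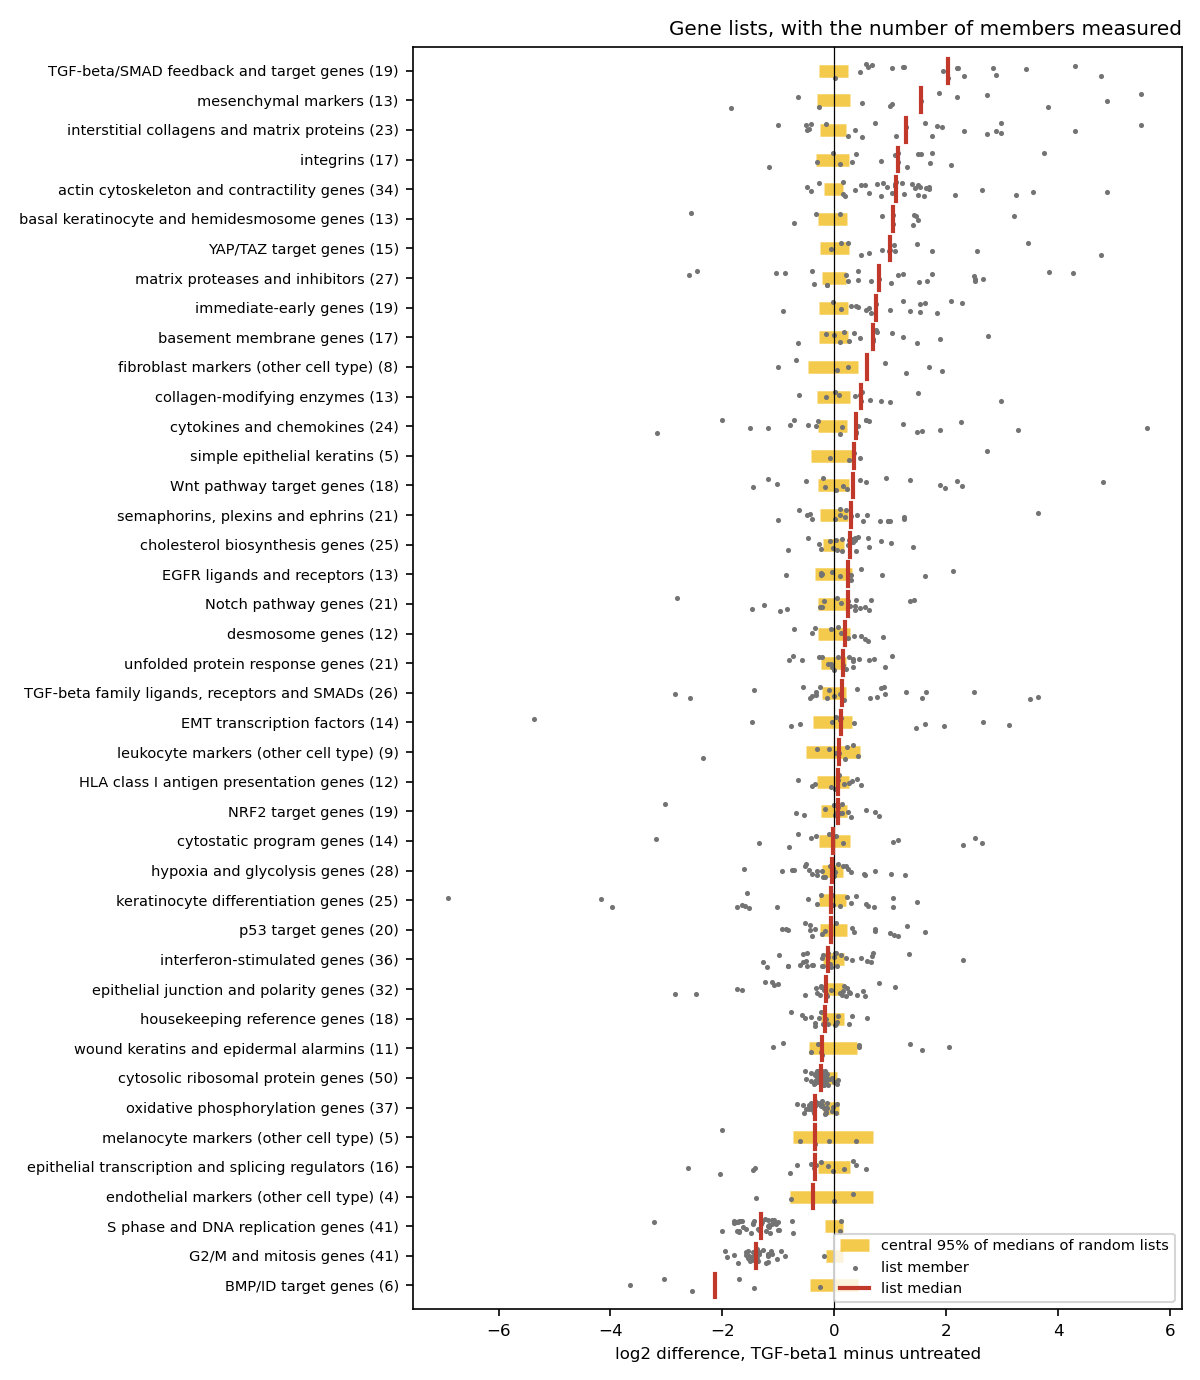
Each grey point is the log2 difference, TGF-beta1 minus untreated, of a measured member of a gene list, the red bar is the list median and the yellow band holds the central 95% of medians of matched random lists; points are spread vertically for legibility, and genes not reported here are not drawn. Medians run from −2.13 for BMP/ID target genes to 2.03 for TGF-beta/SMAD feedback and target genes.

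Cell cycle genes were lower almost throughout. The median of S phase and DNA replication genes was −1.31, below every random list: 36 of 41 were at least 2-fold lower and none was as much higher. MCM10 (−1.75), TYMS (−1.80) and MCM5 (−1.70) were lower, while MYC lay close to 0 (0.12). The median of G2/M and mitosis genes was −1.40, also below every random list, with 38 of 41 at least 2-fold lower, including NDC80 (−1.92), TOP2A (−1.52) and the proliferation marker MKI67 (−1.53). Cytostatic program genes had no common direction, with a median of −0.03 over 14 genes (41.9th percentile, of the other sign with median centring). The cyclin-dependent kinase inhibitor genes CDKN2B (2.64; 1.39 with normexp) and CDKN1A (1.14; 0.67) and the stress genes GADD45A (2.52) and GADD45B (2.30) were higher, whereas another inhibitor gene, CDKN1C, was lower (−3.19; −1.87 with normexp). Of 20 p53 targets, 5 were at least 2-fold higher, TP53INP1 (1.61) the most, around a median of −0.07 (30.4th percentile) that had the other sign with median centring and with the mean of all probes.

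Of 24 cytokine and chemokine genes, 7 were at least 2-fold higher and 4 lower, around a median of 0.39 (99.9th percentile; 0.14 with normexp background correction and 0.20 without a filter on dim probes). Besides IL6, IL11 (3.28) and IL1B (1.48) were higher, and CCL2 (−3.17; −2.01 with normexp) and TNFSF10 (−1.19) were lower. Immediate-early genes had a median of 0.74, above every random list, with JUN (2.28) and FOSB (2.08; 1.26 with normexp) highest. The list of Wnt targets also holds Wnt ligand and receptor genes, so its median is not one of targets alone. That median was 0.34 (99.5th percentile, and 0.20 without a filter on dim probes), with 6 of 18 members at least 2-fold higher and 3 lower. Among those higher were the ligand genes WNT5B and WNT5A. The 2 probes of WNT7B that were well above background disagreed in sign, at 1.97 and −0.98. Semaphorins, plexins and ephrins had a median of 0.29 (99.0th percentile), with SEMA7A higher by 3.63 (2.27 with normexp). In the Notch list (0.23, 97.3th percentile, mean −0.06) 2 of 21 members were at least 2-fold higher, HEY2 (at least 1.42; 0.43 with normexp) and LFNG (1.35; 0.90 with the mean of all probes), and 3 were at least 2-fold lower, including NRARP (−2.81) and NOTCH3 (−1.47). The Notch median was 0.084 with normexp background correction. In the list of EGFR ligands and receptors, which also holds feedback genes (0.24, 94.4th percentile; 0.11 with normexp), the ligand gene AREG (1.62) and DUSP6 (2.11), which encodes a MAP kinase phosphatase, were past 2-fold.

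Metabolic and stress lists moved little. Oxidative phosphorylation genes had a median of −0.34 at the 0.01th percentile and cytosolic ribosomal protein genes −0.24 at the 0.32th, yet none of their 37 and 50 members reached 2-fold. With median centring these medians were −0.23 and −0.12, and the ribosomal one was −0.16 with quantile normalization and −0.15 with the authors' processed values. Cholesterol biosynthesis genes had a median of 0.28 (99.8th percentile), with STARD4 (1.40, but 0.91 with normexp) and MSMO1 (1.02, but 0.74 at the lowest over the alternatives) past 2-fold. Medians within the central 95% of random lists were found for unfolded protein response genes (0.15), NRF2 targets (0.05), HLA class I presentation genes (0.07) and housekeeping genes (−0.18), and for hypoxia and glycolysis genes (−0.05) and interferon-stimulated genes (−0.11), whose medians had the other sign with median centring. Among NRF2 targets AKR1B10, which has a near-identical paralog, was lower (−3.02; −1.96 with normexp). Of 36 interferon-stimulated genes, GBP1 (2.29; 1.35 with normexp) and TRIM22 (1.34; 0.81) were at least 2-fold higher and MX1 (−1.27; −0.69 with normexp) and OAS3 (−1.21; −0.61 with the mean of all probes) at least 2-fold lower. Markers of other cell types were measured in small numbers. The fibroblast list had a median of 0.58 (8 of 16 measured, 99.4th percentile; 0.25 with genes well above background on both arrays only and 0.19 without a filter on dim probes), with TCF21 (at least 1.92; 0.60 with normexp), C1S (1.68; just past 2-fold with normexp) and COL1A1 at least 2-fold higher and FBLN1 lower. Melanocyte markers (−0.35, 5 genes, 18.3th percentile), leukocyte markers (0.09, 9 genes, 72.0th percentile) and endothelial markers (−0.39, 4 genes, 15.8th percentile, of the other sign without a filter on dim probes) lay within the central 95%. In each of these lists 1 member was at least 2-fold lower and none as much higher.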

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

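Transcripts known only by a clone, locus or transcript identifier were left out of the gene counts and are described here because no comparison above used them. Of 4946 such transcripts with a measured signal, 279 (5.64%) were at least 2-fold higher with TGF-β1 and 308 (6.23%) at least 2-fold lower. These shares were slightly below the 6.12% and 6.80% of genes with a symbol. Of the same transcripts, 362 were well above background with TGF-β1 only and 734 in untreated cells only, against 3850 on both arrays. Genes with a symbol leaned the same way, with 331 and 714 against 13844. The highest measured on both arrays was ENST00000439784, at 4.57 (chromosome 7, hg19 98908665 to 98908724), and the next was the probe A_33_P3381305, at 3.91 (chromosome 14, hg19 104670847 to 104670906). The lowest was ENST00000427543, at −4.28 (chromosome 14, hg19 106066443 to 106066502), with ENST00000420153 close by at −4.21 (chromosome 14, hg19 106066252 to 106066311). With 1 array per group these values have no replicate check, and no explanation for them was tested.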

How the results depend on the processing

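No list median outside the central 95% of random lists had the other sign under any of the 11 alternatives, and nor did any of the 308 named genes past 2-fold where it had a value: 29 of them have none when both arrays must be well above background. Median centring, spike-in scaling and the percentile over detected probes shift all differences by a constant. They moved the median of all genes by 0.11, −0.046 and 0.009, too little to turn these signs. Requiring both arrays well above background leaves the values of single genes as they are. These settings therefore could not have turned the sign of a gene past 2-fold. Of the 11, the percentile over detected probes and spike-in scaling, were 2 chosen after seeing the data. No paired analysis was possible because each group has 1 array. Over all alternatives, 43 list medians moved by more than the SD of random medians and 419 did not; 229 named-gene values moved by more than the scanner's error, 153 of them with normexp. Leaving out saturated spots removed nothing, so it tests nothing. The higher and lower counts were 479 and 508 with normexp, whose offset shrinks differences of dim genes, and 1562 and 1741 without a filter on dim probes, which adds genes to reach 22826. In the other alternatives they ran from 751 to 1096 and from 834 to 1082. Median centring moved the median of all genes by 0.11, so changes there are relative to that shift; higher genes were 56.8% of those past 2-fold, against 47.3%. Signal over background sets the limit for dim genes. Unless stated, the cause was not tested.

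With normexp the medians were 1.77 for TGF-β/SMAD targets, 1.18 for mesenchymal markers, 0.68 for interstitial matrix, 0.28 for basement membrane, 0.37 for proteases, 0.70 for integrins, 0.96 for actin genes, −1.19 for S phase, 0.14 for cytokines, 0.53 for immediate-early genes, 0.084 for Notch and 0.26 for fibroblast markers. With median centring, which adds a constant, they were 0.25 for the TGF-β family list, −0.033 for epithelial junctions, 0.92 for proteases and 1.21 for actin genes. Also with median centring they were −1.19 for S phase, −1.28 for G2/M, 0.0004 for interferon-stimulated genes, 0.26 for the unfolded protein response and 0.067 for hypoxia. In the same setting they were 0.40 for cholesterol synthesis, −0.23 for oxidative phosphorylation, −0.12 for ribosomal proteins and −0.06 for housekeeping genes. Without a filter on dim probes they were −1.58 for BMP/ID targets, 1.01 for mesenchymal markers, 0.14 for differentiation, 0.18 for wound keratins, 0.37 for interstitial matrix, 0.42 for proteases, 0.96 for integrins, 0.20 for cytokines, 0.20 for Wnt targets, 0.19 for fibroblast and 0.20 for endothelial markers. With genes well above background on both arrays they were 1.45 for interstitial matrix, 0.25 for fibroblast and −0.77 for endothelial markers. The mean of all probes gave 0.67 for proteases. Ribosomal proteins stood at −0.16 with quantile normalization, −0.17 with loess and −0.15 with the authors' processed values. Medians of 7 lists, none outside the central 95% of random lists, had the other sign in at least 1 alternative.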

Other observations

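Except for the count of transcripts named after a gene, the tests in this part were chosen after the patterns had been seen, and so were the genes named here. Outside the lists, single genes with large differences are given as values. The pregnancy-specific glycoprotein genes PSG2 (2.69), PSG3 (2.80), PSG5 (2.88) and PSG8 (2.77) and the chorionic gonadotropin gene CGB3 (3.80) were higher with TGF-β1, while the placental alkaline phosphatase gene ALPP was lower (−3.19). These genes have near-identical copies, so which member gave the signal is uncertain. ODAPH and AMTN, a pair of genes known from enamel formation and located on chromosome 4, were both among the largest bounds. The vasoconstrictor gene EDN1 was higher by 3.20, the parathyroid hormone-related gene PTHLH by 3.01, the cyclin gene CCND2 by 2.76 and the lymphangiogenic factor gene VEGFC by 2.12. The transcription factor gene MYB (−2.88), the dipeptidyl peptidase gene DPP4 (−3.17), the sodium channel gene SCNN1A (−2.89) and the receptor gene FGFR3 (−1.78) were lower.

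Some genes gave opposite answers on different probes. In 3726 genes with several probes on both arrays, 26 had probes whose differences lay more than 2 apart. Of 493 with a probe past 2-fold, 429 (87.0%) had all probes in the same direction and 6 had probes past 2-fold in opposite directions. Every probe was past 2-fold in the same direction in only 193 of the 493. In the others, whether the gene passed 2-fold, or in which direction, depended on the probe. ANTXR2 was at −0.18 and 3.38, KIFC3 at −0.86 and 1.88, CBX7 at −1.17 and 1.32, and EXOC7 ran from −2.04 to 0.39 over 4 probes. No explanation was tested for these.

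The S phase and mitosis genes were lower with TGF-β1. Spike-in scaling, which left the median of the 82 genes at −1.43, argues against the scaling between the arrays as the whole cause, and loess, which left it at −1.36, against a trend with signal. Spike-ins do not measure RNA per cell. Another difference between the cultures, such as density, cannot be told apart from TGF-β1, because there was 1 culture per group. A slower cell cycle with TGF-β1 may therefore be one of several causes, and stays a hypothesis.

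Core histone genes did not behave alike. Of 41 H2A, H3 and H4 genes, 31 were at least 2-fold lower, with a median of −1.47, whereas 16 H2B genes had a median of −0.17, from H2BC7 at −2.78 to H2BC12 at 1.97. A lower share of cells in S phase as the whole cause would lower the families alike. The H2B median lay 1.30 above that of the other families, with a 95% bootstrap interval over genes of 0.33 to 1.77, which leaves out 0 but reaches below the 0.5 set as alike. These genes are not independent replicates, so the interval holds no variation between cultures or arrays and may be too narrow. H2B was also picked for standing apart, so this stays open. Probes that pool near-identical H2B copies stay open as well: the SD among H2B genes was 1.19, and that between probes of a core histone gene 1.34 (12 genes), too wide to decide. Probes of H4C8 gave −1.20 and 3.48, of H2AC6 −1.82 to 1.44, and of H2AC11 −2.64 and 0.09. Replication-dependent histone transcripts usually lack the poly(A) tail that labelling kits of this kind prime on, so longer polyadenylated transcripts with TGF-β1 are a candidate explanation; the more downstream probe had the higher difference in 6 of 9 genes with several probes on a transcript, by at least 3.62 in H2BC21 and by 1.73 in H2BC12, which leaves it open.

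Neighbouring genes on a chromosome were past 2-fold in the same direction in 248 of 14725 pairs. The highest of 1000 shuffled gene orders gave 157, which argues against chance order. Paralogs with a shared symbol stem, the whole opening run of letters, can share probe signal but do not account for all of it. Without such pairs and those with a hyphen in a symbol, as in antisense names, 161 of 12632 pairs remained. That is above the highest shuffle of 136, and 84 ran in opposite directions. Related genes with differing stems stayed in, such as LHB (1.69) with CGB3 (3.80) and PTPRB (2.01) with PTPRR (3.58). Paralogs as a whole are therefore not excluded. The remaining pairs in the same direction include MMP2 (2.52) with LPCAT2 (2.11), TNC (2.72) with PAPPA (2.29) and KPNA7 (4.29) with MYH16 (3.23). ME3 (3.18) with PRSS23 (3.16) is another, but the 2 probes of PRSS23 were at 0.86 and 3.16. Local regulation that also reaches non-coding transcripts was tested on 1241 lnc transcripts and the genes they are named after: 18 pairs were past 2-fold in the same direction and 7 in opposite directions, where shuffles gave 10.5 and 10.6 on average. By the criterion set beforehand, a count within the range of the shuffles, whose highest was 21, spoke against it. That bound was too wide, since 9 of 1000 shuffles reached 18 around an SD of 2.97, so in a reading changed after the count was seen the explanation stays open. Transcripts that overlap or read through into a neighbour were not separated.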
